A study of Macaca mulatta with 12 samples.

How the data were processed

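RNA was extracted from cultures labelled as cardiomyocytes derived from rhesus macaque induced pluripotent stem cells, kept as monolayer or as EHT, in normoxia or after hypoxia, with 3 libraries in each of 4 groups. The labels name RNeasy kits for extraction, the Ion Total RNA-Seq Kit v2 for libraries and the Ion Proton for sequencing. The labels give hypoxia as an anaerobic pouch for 24 hours and then 24 hours following a change of medium, and they do not say when RNA was taken. Per the labels, reads were aligned with HISAT2, counted per gene with featureCounts and transformed with DESeq2. Their versions, the genome build and the annotation are not given in the sources used here, so genes are identified by symbol alone and carry no positions. Of the 16745 symbols, 15444 matched a symbol of the reference list.

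The deposited table holds variance-stabilised values on a log2 scale, made by the authors with DESeq2. The lowest value, 3.00, was shared by every gene with 0 reads. Inverting the transformation gave whole read counts within a tolerance of 0.01 for 100% of values in every library. Recovered totals were 4154346 to 11298841 reads per library. In all, 1595 genes had 0 reads in every library and 10760 had a read in each. The scaling factors in the deposited values, divided by median-of-ratios factors from the recovered reads, ran from 0.412 to 1.42. Reads are not independent molecules, so bounds based on 0 reads cover counting error alone. Log2 differences of genes with few reads understate their folds, because the transformation flattens low values.

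Genes whose mean over the 12 libraries lay at least 1 log2 unit above the lowest value were tested, 12084 in all. The genes MYH7, TTN, NPPB, LDHA, GAPDH and MKI67 are absent from the table and MYL2 lay under the filter, so these were not analysed here. A linear model with 1 mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend. The 5 comparisons were EHT against monolayer in each oxygen condition, hypoxia against normoxia in each culture, and the interaction. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The prior degrees of freedom of the variance model were infinite on the deposited values, so all genes shared 1 trended variance. After centring each library on its median they were 4.77, and standard errors ran from 0.10 to 1.80 for the comparisons of groups.

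Lists of genes and of cell type markers were fixed, 42 in all, and 41 had a gene that could be tested. They were tested with camera from limma, a competitive test, with a preset correlation of 0.01 between genes and adjustment over all lists of a comparison. The correlation was also estimated from the data, and fry was run as a self-contained test. For each list the text gives the members called over all genes tested and those called when adjusted over the list alone. Members are counted out of those that passed the filter on low values. Lists share members. Shares of reads per list were compared by exact permutation tests, two-sided, for which the smallest p with 3 against 3 libraries is 0.1.

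The lists, the groups, the tests, the first set of alternatives and the rule for naming genes were chosen before the data were examined. The rule took, in each direction, the 8 genes with the largest difference among those called, whose groups did not overlap and whose mean lay at least 2 log2 units above the lowest value. The interaction had no condition on overlap. The rule added up to 3 members with the smallest p per list and direction, and a set of cardiac, matrix and hypoxia genes fixed by name. The text gives most genes of the first part and examples of the others.

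The first alternatives were median centring, quantile normalization, filters, variance models, array weights, the replicate number as a block, fits to the compared groups alone, and leaving out each library in turn. Added after the data were seen were median-of-ratios scaling, voom on the recovered reads, leaving out both EHT libraries numbered 3, that omission with centring, and centring with an estimated correlation. The replicate number was tested as a pairing between groups. For EHT normoxia and hypoxia the correlation of libraries sharing a number, after subtracting group means, was 0.04, 0.33 and 0.27, and no pairing was used in the reported fits. Figures were drawn with matplotlib 3.10.9.

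The fit was tested on simulated counts with 200 changed genes and a dispersion of 0.05. With the library offsets seen in the deposited values, it recovered 5.97% of 2-fold, 46.3% of 4-fold and 100% of 8-fold changes for EHT against monolayer in normoxia. After centring it recovered 47.8% of 2-fold changes. For the interaction it recovered 25.4% of 4-fold changes with the offsets and 89.6% after centring.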

Results

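RNA was sequenced from cultures labelled as cardiomyocytes made from rhesus macaque induced pluripotent stem cells and kept either as a flat monolayer or as engineered heart tissue (EHT), a small strip of tissue cast in 3 dimensions. Each culture was kept in normal oxygen (normoxia) or put in an oxygen-depleted pouch for 24 hours, after which the labels give another 24 hours following a change of medium (hypoxia). They do not say when RNA was taken, and no hours after a medium change are recorded for normoxia. Oxygen and the medium change therefore cannot be told apart in the hypoxia comparisons or the interaction. The 4 groups held 3 libraries each, 12 in all. The table listed 16745 genes by symbol, and inverting its transformation returned 4154346 to 11298841 reads per library. Between 11784 and 14372 genes had at least 1 read in a library. Whether replicates were separate differentiations is not stated, so p-values cover no more than the spread between these samples. On the deposited values that spread was 1 trended variance shared by all genes, not the spread of each gene.

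In the plot of the libraries on the first principal components, culture and oxygen separated the 12 libraries after each was centred on its median. The first component held 40.2% of the variance and the second 28.3%. Monolayer libraries lay between -62.90 and -35.02 on the first component, and EHT libraries lay between 24.63 and 79.58. On the second, hypoxia libraries lay between -55.00 and -16.74 and normoxia libraries between 32.96 and 51.32. EHT hypoxia replicate 3 stood apart from its group at 79.58 and -16.74, against 24.63 and 24.86 on the first component for the other EHT hypoxia libraries.

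**Figure D1:**
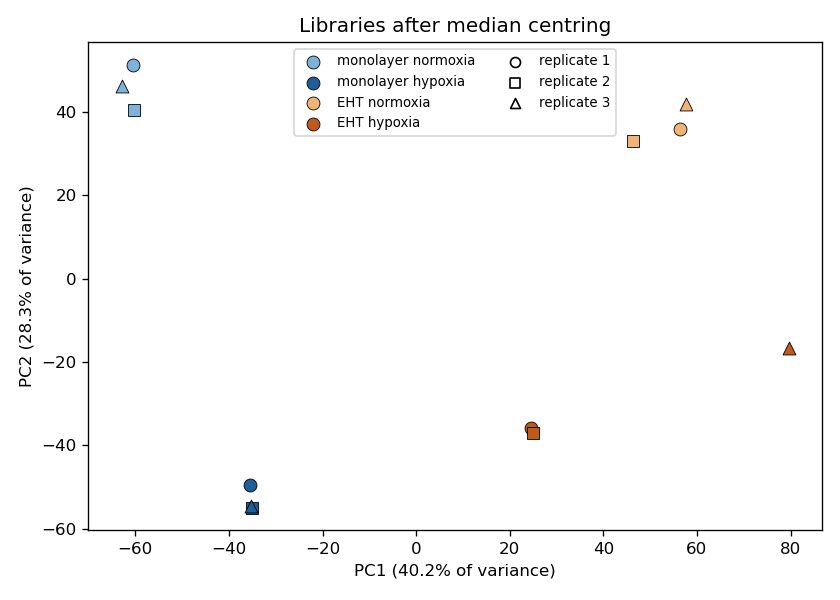
Coordinates of the 12 libraries on the first and second principal components (log2 units) of 12084 genes after median centring; colours mark the 4 groups and shapes the replicate number. Monolayer and EHT libraries separate on the first component, with 40.2% of the variance, and oxygen on the second, with 28.3%.

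The level of the deposited values differed between libraries. Over the 12084 genes tested, library medians ran from 6.98 to 8.75, and the highest belonged to monolayer normoxia replicate 3. Centring every library on its median added 0.74 to the log2 difference between EHT and monolayer in normoxia, 0.04 to that in hypoxia, 0.55 to the hypoxia difference in monolayer and -0.15 to that in EHT. It added -0.70 to the interaction. Standard errors of the log2 differences on the deposited values were 0.46 to 0.60, and 0.65 to 0.85 for the interaction, with n = 3 per group. They were close to equal for all genes, and the smallest call was 1.15 on the log2 scale. Where centring changed the calls of a list described below, its centred counts follow the deposited ones.

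The comparison of EHT with monolayer in normoxia asked how expression differed between the culture formats without hypoxia. Genes of the contractile apparatus were lower in EHT. MYH6, the alpha heavy chain of cardiac myosin, fell by 5.48 ± 0.48 (SE, n = 3 per group, adjusted p = 3.1e-28), and stood at -4.75 ± 1.63 after centring (adjusted p = 0.0329). The genes of cardiac troponin T (TNNT2, -4.37), the atrial-type myosin light chain (MYL7, -5.30), slow skeletal-type troponin I (TNNI1, -4.42) and the calcium release channel (RYR2, -3.69) were lower too. NPPA, which encodes atrial natriuretic peptide, differed by 0.44 (adjusted p = 0.521), and PLN, which encodes the calcium pump inhibitor phospholamban, by 0.17 (adjusted p = 0.815). Leaving out 1 library moved NPPA between -0.55 (EHT normoxia replicate 1) and 1.63 (EHT normoxia replicate 3, adjusted p = 0.0242), and PLN between -0.85 (monolayer normoxia replicate 3) and 0.91 (monolayer normoxia replicate 2). Of the cardiomyocyte marker list 6 of 8 were lower, also adjusted over the list alone and after centring (camera adjusted p = 4.3e-08; adjusted p = 0.222 with an estimated correlation and 0.0417 after centring). Cardiomyocyte markers together took 0.143 ± 0.104% (SD, n = 3) of the reads in monolayer normoxia and 0.00761 ± 0.00615% in EHT normoxia (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow). Fibroblast markers took 5.03 ± 1.88% in monolayer normoxia and 5.86 ± 0.583% in EHT normoxia (SD, n = 3, exact permutation p = 0.6, two-sided).

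The genes with the lowest values in EHT relative to monolayer were mostly epithelial. KRT5, KRT15 and KRT17, keratins of basal epithelium, differed by -8.94, -8.24 and -8.68, and the hemidesmosome collagen COL17A1 by -7.18. GABRP, a subunit of the GABA-A receptor, and KRT4, a keratin of stratified epithelium, had no read in EHT normoxia. Against 3 reads over that group, their counts per library total (CPM) were at least 4473-fold and at least 2441-fold higher in monolayer normoxia. The secreted protein gene WFDC2 (-6.85) and CRABP1, which encodes a retinoic acid binding protein (-8.37), were also lower. Higher in EHT were the transcription factor MSC (5.21), TNFSF18 (4.98) and CD70 (4.63) of the tumour necrosis factor family, and LTBP2, which binds latent TGF-beta (4.90). The thrombin receptor family member F2RL2 (4.57), FAM20A (4.53) and the Wnt antagonist SFRP2 (4.52) were higher too. PRR4 had no read in monolayer normoxia, and its CPM were at least 628-fold higher in EHT normoxia.

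**Figure D2:**
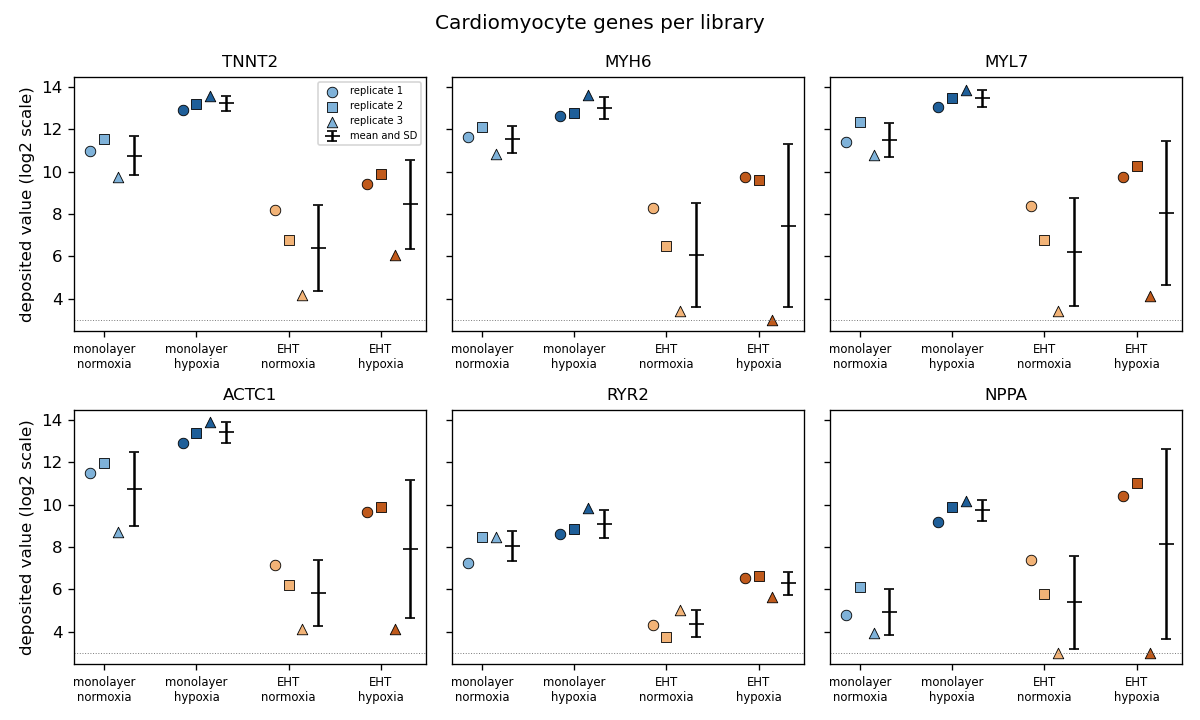
Deposited values (log2 scale) of 6 cardiomyocyte genes in each library; shapes mark the replicate number, bars give the mean and SD of 3 libraries, and the dotted line marks 0 reads. EHT hypoxia replicate 3 has no MYH6 or NPPA read, while MYH6 lies at 9.73 and 9.61 in the other EHT hypoxia libraries.

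Among the lists fixed in advance, that of sarcomere and Z-disc genes had 20 of 26 members lower in EHT and 1 higher, the same counts as adjusted over the list alone (camera adjusted p = 8.2e-14; adjusted p = 0.222 with an estimated correlation, and after centring 15 lower and 2 higher). DES, the muscle intermediate filament, was lowest at -6.60, and NEXN was the member that was higher (1.58). Of the intercalated disc and costamere genes 10 of 18 were lower and 0 were higher, again the same counts as adjusted over the list alone (camera adjusted p = 6.8e-04; adjusted p = 0.378 with an estimated correlation, and after centring 6 lower and 4 higher). The desmosome genes DSP (-6.03), DSC2 (-5.38) and DSG2 (-3.71) had the smallest p-values there, and epithelium expresses them as well. Cardiac transcription factors were lower in 14 of 19 members, as many as adjusted over the list alone, HAND1 (-4.73) and HOPX (-3.64) among them (camera adjusted p = 2.4e-04; adjusted p = 0.378 with an estimated correlation, and after centring 11 lower and 2 higher). All 4 ventricular markers measured were lower, also when adjusted over the list alone (camera adjusted p = 3.4e-05; adjusted p = 0.0374 with an estimated correlation, and after centring 3 lower). Ion channel and gap junction genes were lower in 15 of 22 and higher in 1, with the same counts adjusted over the list alone (camera adjusted p = 0.00393; adjusted p = 0.569 with an estimated correlation, and after centring 10 lower and 4 higher). This list took 0.0802 ± 0.00675% of the reads in monolayer normoxia and 0.127 ± 0.0197% in EHT normoxia (SD, n = 3, exact permutation p = 0.1, two-sided). Of these, the connexin gene GJA1, chosen after its values were seen, took 0.0454% and 0.113%, and the rest of the list 0.0348% and 0.0140%. Natriuretic peptide and stretch-response genes went both ways, with 4 of 13 higher and 3 lower, 5 and 3 adjusted over the list alone and 7 and 0 after centring (camera adjusted p = 0.00288, higher; adjusted p = 0.378 with an estimated correlation). They took 0.165 ± 0.0164% of reads in monolayer normoxia and 1.31 ± 0.596% in EHT normoxia (SD, n = 3, exact permutation p = 0.1, two-sided). Of these, TIMP1 (3.91), chosen after its values were seen, took 0.0508% and 1.05%, and the rest of the list 0.114% and 0.268%.

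Genes of proliferation and sterol synthesis were also lower in EHT. Of the cell cycle list 28 of 30 genes were lower and 0 were higher, the same counts as adjusted over the list alone (camera adjusted p = 1.3e-13; adjusted p = 0.378 with an estimated correlation, and after centring 28 lower and 1 higher). TOP2A, a topoisomerase of dividing cells, stood at -3.75 and the kinetochore gene CENPF at -3.54. The cholesterol synthesis list had 16 of 19 lower, 17 adjusted over the list alone, with HMGCS1 (-2.83) among them (camera adjusted p = 1.4e-04; adjusted p = 0.569 with an estimated correlation). In the glycolysis list 10 of 15 were lower, 12 adjusted over the list alone, among them ALDOC (-3.66) and the glucose transporter SLC2A1 (-2.88; camera adjusted p = 0.0017; adjusted p = 0.569 with an estimated correlation). The hypoxia marker CA9, a carbonic anhydrase, was lower at -4.07, as was the mitophagy gene BNIP3 at -2.09. The list of hypoxia-inducible genes outside glycolysis, which holds both, was not among the lists called. It took 0.563 ± 0.117% of the reads in monolayer normoxia and 0.616 ± 0.0975% in EHT normoxia (SD, n = 3, exact permutation p = 0.6, two-sided). Its member VEGFA differed by -0.25 (limma adjusted p = 0.729).

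Matrix remodelling enzymes and inhibitors were higher in 11 of 20 and lower in 3, with 12 higher adjusted over the list alone (camera adjusted p = 1.1e-08; adjusted p = 0.252 with an estimated correlation, and after centring 15 higher and 3 lower). The metalloproteinase inhibitors TIMP1 (3.91) and TIMP3 (3.81) were higher, and the protease ADAMTS9 (-3.66) was lower. Of the collagens and extracellular matrix genes 4 of 29 were higher and 5 lower, 5 and 6 adjusted over the list alone (camera adjusted p = 2.4e-04; adjusted p = 0.569 with an estimated correlation and 0.0734 with centring as well). Centring turned this into 18 higher and 3 lower. COL1A1 differed by 0.94 (adjusted p = 0.211) on the deposited values and by 1.68 (adjusted p = 0.00137) after centring. Without monolayer normoxia replicate 3 its deposited difference was 1.54 (adjusted p = 0.0365). The p53 target CDKN1A, an inhibitor of cell division, was higher by 1.57. In the p53 list 4 of 21 were higher and 2 lower, the same adjusted over the list alone, and centring made that 17 and 0 (camera adjusted p = 4.7e-05; adjusted p = 0.569 with an estimated correlation). The call of CDKN1A was lost (1.39, adjusted p = 0.0505) without EHT normoxia replicate 1.

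Markers of other cell types moved with culture as well. The epithelial marker list had 5 of 6 lower in EHT, 6 adjusted over the list alone, including EPCAM (-6.44) and CLDN4 (-5.77; camera adjusted p = 5.5e-18; adjusted p = 0.00237 with an estimated correlation). All 7 epicardial markers measured were lower, also when adjusted over the list alone, with UPK1B at -5.27 and BNC1 at -5.21 (camera adjusted p = 7.2e-07; adjusted p = 0.131 with an estimated correlation, and after centring 3 lower). As fixed, the epicardial and epithelial lists both name KRT19, and their tests do not separate epicardial from epithelial expression. Endoderm or hepatic markers, 11 in the table, were lower in 4 of 5 tested and higher in 1, the same adjusted over the list alone. For this list camera gave an adjusted p of 0.00918, 0.41 with an estimated correlation, 0.123 after centring and 0.0758 without monolayer normoxia replicate 3, and centring left 3 lower and 1 higher. AFP, the fetal liver protein, had no read in EHT normoxia, and its CPM were at least 705-fold higher in monolayer normoxia. The 11 endoderm or hepatic genes together took 0.0171 ± 0.0101% of the reads in monolayer normoxia and 0.0151 ± 0.0109% in EHT normoxia (SD, n = 3, exact permutation p = 0.7, two-sided). All 3 pluripotency markers measured were lower, also adjusted over the list alone, with SOX2 at -3.48 (camera adjusted p = 0.0161; adjusted p = 0.269 with an estimated correlation and 0.0661 after centring). Fibroblast markers went both ways, with S100A4 (4.38) and PDGFRB (1.43) higher and TCF21 (-1.91) and DCN (-1.33) lower among 10, the same adjusted over the list alone. DCN was not called after centring (-0.59, adjusted p = 0.18). The median of that list was -0.48, and 0.26 after centring, while its mean and test were positive (camera adjusted p = 0.0248; adjusted p = 0.613 with an estimated correlation, 0.109 without monolayer normoxia replicate 1 and 0.127 after centring, when 4 were higher and 1 lower). When 1 library was left out, calls were lost for PDGFRB (adjusted p = 0.0558 to 0.142) without monolayer normoxia replicate 1 or 2 or EHT normoxia replicate 1 or 3, for DCN (adjusted p = 0.0877 to 0.498) without monolayer normoxia replicate 3 or EHT normoxia replicate 2 or 3 and for TCF21 (-1.29, adjusted p = 0.0542) without monolayer normoxia replicate 3.

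In the limma fit 3424 of 12084 genes passed an adjusted p of 0.05 (Benjamini-Hochberg), 325 higher and 3099 lower in EHT. After centring 4984 passed, 2750 higher and 2234 lower, and 2491 genes were called both ways. With the correlation between genes estimated, 2 of the 25 lists called by camera held, those of epithelial and ventricular markers, and with centring as well their adjusted p were 0.111 and 0.343. The troponin gene TNNI3 (-1.72, adjusted p = 0.00217) lost its call after centring (-0.98, adjusted p = 0.26) and without monolayer normoxia replicate 3 (-1.17, adjusted p = 0.158). Further lists were called by camera and are given with members higher and lower. In parentheses stand the same counts after centring and the adjusted p with an estimated correlation. Called higher were unfolded protein response 1 and 0 (13 and 0, 0.613), NF-kB and cytokines 3 and 3 (6 and 2, 0.495) and skeletal muscle markers 1 and 1 (1 and 0, 0.269). Called lower were fetal or smooth-type isoforms 0 and 6 (1 and 4, 0.211), calcium handling 0 and 11 (1 and 6, 0.569) and atrial markers 0 and 5 (2 and 4, 0.569). When 1 library was left out, calls were lost for calcium handling (adjusted p = 0.0753 to 0.223) without monolayer normoxia replicate 1 or 2 or EHT normoxia replicate 3. They were lost as well for atrial markers (adjusted p = 0.136 to 0.413) without monolayer normoxia replicate 2 or 3 or EHT normoxia replicate 3 and for skeletal muscle markers (adjusted p = 0.0758) without monolayer normoxia replicate 3.

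The comparison of EHT with monolayer in hypoxia asked the same of the cultures after oxygen depletion. Contractile genes were again lower in EHT. MYH6 fell by 5.56 ± 0.48 (SE, n = 3 per group, adjusted p = 8.8e-28), and stood at -5.53 ± 1.63 after centring (adjusted p = 0.0178), with no MYH6 read in EHT hypoxia replicate 3 (-3.34 without it). The cardiac actin ACTC1 (-5.53), MYL7 (-5.43), TNNT2 (-4.77), the light chain MYL4 (-4.75) and RYR2 (-2.82) were lower as well. CRABP1 (-7.78), the smooth muscle actin ACTG2 (-4.91) and the muscle and neuron translation factor EEF1A2 (-4.70) were lower too. Higher in EHT were the cytokine IL6 (5.40), the proteoglycan SRGN (5.48), the lectin CLEC2B (4.96), C10orf10 (4.78) and PRR4 (4.77). NDUFA4L2, a respiratory complex subunit induced by hypoxia (4.68), and the protease ADAM8 (4.47) were higher too.

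Cardiomyocyte markers took 0.390 ± 0.0274% of the reads in monolayer hypoxia (SD, n = 3) and 0.0495 ± 0.0421% in EHT hypoxia, where replicates 1, 2 and 3 held 0.0634%, 0.0829% and 0.00231% (exact permutation p = 0.1, two-sided, the smallest possible). Fibroblast markers took 4.60 ± 0.285% in monolayer hypoxia and 6.09 ± 0.858% in EHT hypoxia (SD, n = 3, exact permutation p = 0.1, two-sided). Of the cardiomyocyte marker list 7 of 8 were lower, 8 adjusted over the list alone (camera adjusted p = 1.3e-24; adjusted p = 0.0336 with an estimated correlation, and after centring 6 lower). Of the sarcomere and Z-disc list 19 of 26 were lower and 2 higher, with 20 and 2 adjusted over the list alone (camera adjusted p = 1.3e-31; adjusted p = 0.0336 with an estimated correlation). TCAP, of the Z-disc, was among the higher members (1.54). Its call was lost (adjusted p = 0.0567 to 0.0886) without monolayer hypoxia replicate 1, 2 or 3 or EHT hypoxia replicate 2. Fetal or smooth-type isoforms were lower in 6 of 8 and higher in 1, with 7 and 1 adjusted over the list alone (camera adjusted p = 1.2e-16; adjusted p = 0.0336 with an estimated correlation). In the list of cardiac transcription factors 13 of 19 were lower, 14 adjusted over the list alone, with NKX2-5 at -3.74 and GATA4 at -3.25 (camera adjusted p = 2.1e-10; adjusted p = 0.111 with an estimated correlation). Calcium handling genes were lower in 6 of 20, 9 adjusted over the list alone, including the sodium-calcium exchanger SLC8A1 (-3.39; camera adjusted p = 5.5e-05; adjusted p = 0.265 with an estimated correlation, and after centring 7 lower).

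Smooth muscle or pericyte markers were lower in EHT in 9 of 10, also adjusted over the list alone, with ACTA2 at -3.73 and CNN1 at -3.23 (camera adjusted p = 3.8e-11; adjusted p = 0.0834 with an estimated correlation). Skeletal muscle markers were higher in all 5 tested of 11 in the table, also adjusted over the list alone, led by the acetylcholine receptor subunit CHRNA1 (2.38; camera adjusted p = 1.6e-05; adjusted p = 0.0506 with an estimated correlation, and after centring 2 higher). Of the NF-kB and cytokine genes 6 of 16 were higher and 0 lower, also adjusted over the list alone, with CXCL8 at 3.55 and CCL2 at 1.80 (camera adjusted p = 2.0e-06; adjusted p = 0.167 with an estimated correlation, and after centring 9 higher). Immediate early genes, which respond within minutes to stimuli, were higher in 7 of 17, 11 adjusted over the list alone, including EGR1 (3.07) and FOSL1 (2.92; camera adjusted p = 6.7e-09; adjusted p = 0.311 with an estimated correlation, and after centring 12 higher). Matrix remodelling genes were higher in 10 of 20 and lower in 1, with 10 and 2 adjusted over the list alone, among them the plasminogen activator PLAU (2.78) and MMP9 (2.61; camera adjusted p = 5.5e-05; adjusted p = 0.348 with an estimated correlation, and after centring 10 higher and 2 lower). The heme oxygenase HMOX1, an oxidant defence enzyme, was higher by 2.00. Its call was lost (1.12, adjusted p = 0.15) without EHT hypoxia replicate 3.

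By limma with Benjamini-Hochberg adjustment 1553 genes passed, 607 higher and 946 lower in EHT. After centring 4602 passed, 2227 higher and 2375 lower, with 1438 called both ways. Without monolayer hypoxia replicate 2 the deposited count was 922. Across genes the culture differences in normoxia and in hypoxia correlated with Pearson r = 0.50 and Spearman rho = 0.45, where genes are not independent replicates, and 720 genes were lower in EHT in both, against 243 expected from independent calls, or 907 against 439 after centring. With an estimated correlation and centring, the adjusted p of the cardiomyocyte, sarcomere and fetal isoform lists was 0.572 for each and that of the ventricular list 0.398. NPPA (-1.59, adjusted p = 0.0136) lost its call after centring, was 0.98 without EHT hypoxia replicate 3 and lost its call without monolayer hypoxia replicate 2 (adjusted p = 0.0943) or 3 (adjusted p = 0.114). Further lists were called by camera and are given with members higher and lower. In parentheses stand the same counts after centring and the adjusted p with an estimated correlation. Called higher were unfolded protein response 5 and 0 (11 and 0, 0.713). Called lower were ion channels and gap junctions 0 and 10 (3 and 10, 0.507), intercalated disc and costamere 0 and 11 (0 and 14, 0.118), cell cycle 1 and 9 (2 and 13, 0.713), ventricular markers 0 and 4 (0 and 2, 0.0336), atrial markers 0 and 5 (1 and 4, 0.285), nodal markers 0 and 3 (0 and 4, 0.348) and neural markers 0 and 2 (1 and 2, 0.216). Without EHT hypoxia replicate 3 calls were lost for ion channels and gap junctions (adjusted p = 0.0564), cell cycle (adjusted p = 0.0669), unfolded protein response (adjusted p = 0.0666) and atrial markers (adjusted p = 0.189).

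The comparison of hypoxia with normoxia in monolayer asked how the flat culture differed after oxygen depletion and the change of medium. Genes known as targets of the hypoxia-inducible factors rose. The vasodilator peptide gene ADM rose by 3.80 ± 0.48 (SE, n = 3 per group, adjusted p = 5.8e-13; 4.35 ± 0.32, adjusted p = 7.5e-07, after centring), the stress gene NDRG1 by 3.82, the carbonic anhydrase CA12 by 3.70, and VEGFA, which drives vessel growth, by 2.41. The nuclear receptors NR1D1 (4.14) and RORA (3.85) of the circadian clock, SNCB (4.19), the chemokine CCL21 (3.85) and NPPA (4.79) rose as well. Epithelial genes fell, with KRT5 at -6.60, KRT15 at -5.91, KRT4 at -5.84, COL17A1 at -5.34, GABRP at -7.20 and VTCN1 at -5.37. The epithelial transcription factors TP63 (-5.33) and GRHL2 (-5.31) fell with them.

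**Figure D3:**
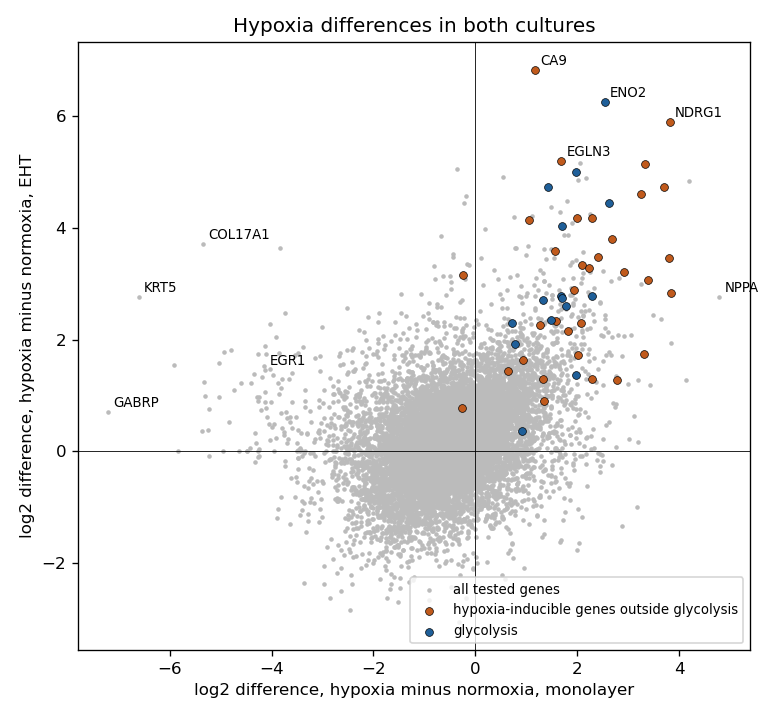
Log2 difference between hypoxia and normoxia for the 12084 tested genes on the deposited scale, in monolayer (horizontal axis) and in EHT (vertical axis); coloured points are the lists of hypoxia-inducible and glycolysis genes. CA9 lies at 1.18 and 6.83. KRT5 lies at -6.60 in monolayer and higher in EHT, with an interaction of 9.36.

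The list of hypoxia-inducible genes outside glycolysis had 27 of 33 members higher and 0 lower, 29 adjusted over the list alone (camera adjusted p = 3.1e-37; adjusted p = 0.189 with an estimated correlation, and after centring 31 up). In the glycolysis list 12 of 15 rose and 0 fell, also adjusted over the list alone, with HK2 at 2.63, ENO2 at 2.54 and PDK1, which slows entry of pyruvate into mitochondria, at 1.71 (camera adjusted p = 2.1e-13; adjusted p = 0.259 with an estimated correlation, and after centring 15 up). CA9 differed by 1.18 (adjusted p = 0.056) on the deposited values and by 1.73 (adjusted p = 0.00894) after centring. Without monolayer normoxia replicate 3 its deposited difference was 2.00 (adjusted p = 0.00181). Collagens and matrix genes rose in 10 of 29 and fell in 2, the same adjusted over the list alone, with NID1 (3.19) and BGN (2.76) up and DCN (-1.62) and LUM (-1.34) down (camera adjusted p = 9.7e-10; adjusted p = 0.432 with an estimated correlation and 0.0111 with centring as well, and after centring 23 up and 2 down). They took 10.8 ± 0.646% of reads in normoxia and 21.99 ± 0.246% in hypoxia (SD, n = 3, exact permutation p = 0.1, two-sided). Of these, the fibronectin gene FN1, chosen after its values were seen, took 2.24 ± 1.05% and 10.4 ± 0.529%, and the rest of the list 8.53 ± 1.59% and 11.6 ± 0.395%. The p53 list rose in 8 of 21 and fell in 1, the same adjusted over the list alone, including MDM2 (2.33) and CDKN1A (1.56; camera adjusted p = 4.1e-05; adjusted p = 0.671 with an estimated correlation, and after centring 13 up and 1 down). When 1 library was left out, calls were lost for DCN (adjusted p = 0.0876 to 0.196) without monolayer hypoxia replicate 1 or monolayer normoxia replicate 3, for LUM (adjusted p = 0.0502 to 0.233) without monolayer hypoxia replicate 1, 2 or 3 or monolayer normoxia replicate 2 or 3 and for CDKN1A (adjusted p = 0.0612 to 0.0649) without monolayer hypoxia replicate 2 or 3.

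Cardiomyocyte markers rose in 6 of 8, 8 adjusted over the list alone, with ACTC1 at 2.69, TNNT2 at 2.47 and PLN at 2.27 (camera adjusted p = 1.4e-12; adjusted p = 0.189 with an estimated correlation and 0.118 after centring). These genes took 0.176, 0.227 and 0.0276% of the reads of monolayer normoxia replicates 1, 2 and 3. Without replicate 3 PLN stood at 1.25, ACTC1 at 1.68 (adjusted p = 0.178), TNNT2 at 1.97 (adjusted p = 0.0564) and the adjusted p of the list at 0.00482. After centring 5 were called. ACTC1 was not (3.24, adjusted p = 0.0954), nor was MYH6 (2.02, adjusted p = 0.336, from 1.47, adjusted p = 0.0126). The deposited call of MYH6 was lost (adjusted p = 0.102 to 0.491) without monolayer hypoxia replicate 3 or monolayer normoxia replicate 3. Cell cycle genes fell in 16 of 30, 22 adjusted over the list alone, the DNA replication genes MCM3 (-3.88) and MCM5 (-3.36) most (camera adjusted p = 4.1e-05; adjusted p = 0.689 with an estimated correlation, and after centring 11 down and 1 up). Cholesterol synthesis genes fell in 14 of 19 and rose in 1, the same adjusted over the list alone, with FDPS at -2.47 (camera adjusted p = 5.5e-04; adjusted p = 0.694 with an estimated correlation, and after centring 16 down and 2 up). Among immediate early genes 9 of 17 fell and 1 rose, with 10 and 1 adjusted over the list alone, with EGR1 at -4.13 and FOS at -2.65 (camera adjusted p = 0.0262; adjusted p = 0.757 with an estimated correlation and 0.124 after centring, when 6 were down and 2 up). These genes took 0.120, 0.122 and 0.501% of the reads of monolayer normoxia replicates 1, 2 and 3. Without replicate 3 the adjusted p of the list was 0.549, EGR1 stood at -2.70 and FOS at -1.26 (adjusted p = 0.0658). Epithelial markers fell in 5 of 6, also adjusted over the list alone (camera adjusted p = 2.0e-10; adjusted p = 0.0193 with an estimated correlation and 0.326 with centring as well). Endoderm or hepatic markers fell in all 5 tested of 11 in the table, also adjusted over the list alone, with AFP at -3.59 (camera adjusted p = 9.6e-05; adjusted p = 0.259 with an estimated correlation, and after centring 4 down).

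In total 2945 genes passed by limma with Benjamini-Hochberg adjustment, 535 up and 2410 down. After centring 5615 passed, 3362 up and 2253 down, with 2405 called both ways. The deposited count was 1611 without monolayer hypoxia replicate 2 and 1699 without monolayer hypoxia replicate 1. Further lists were called by camera and are given with members up and down. In parentheses stand the same counts after centring and the adjusted p with an estimated correlation. Called up were sarcomere and Z-disc 13 and 0 (11 and 0, 0.259), fetal or smooth-type isoforms 5 and 1 (2 and 0, 0.432), calcium handling 2 and 2 (10 and 0, 0.481), intercalated disc and costamere 4 and 3 (9 and 3, 0.689), natriuretic peptides and stretch response 4 and 1 (6 and 0, 0.259), unfolded protein response 4 and 2 (14 and 0, 0.757), NF-kB and cytokines 2 and 2 (7 and 1, 0.689), matrix remodelling 7 and 5 (10 and 4, 0.731) and smooth muscle markers 3 and 0 (6 and 0, 0.426). Called down were epicardial markers 1 and 4 (1 and 4, 0.259) and pluripotency markers 0 and 2 (0 and 2, 0.276). Of these, calls were lost without monolayer normoxia replicate 3 for fetal or smooth-type isoforms (adjusted p = 0.241), calcium handling (adjusted p = 0.0552), intercalated disc and costamere (adjusted p = 0.169), NF-kB and cytokines (adjusted p = 0.169) and matrix remodelling (adjusted p = 0.122). They were also lost for intercalated disc and costamere without monolayer hypoxia replicate 3 (adjusted p = 0.0669), NF-kB and cytokines without monolayer hypoxia replicate 1 or 2 (adjusted p = 0.0561 and 0.068) and pluripotency markers without monolayer normoxia replicate 2 (adjusted p = 0.0624).

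The comparison of hypoxia with normoxia in EHT asked the same of the tissue. CA9 rose by 6.83 ± 0.48 (SE, n = 3 per group, adjusted p = 1.3e-41; 6.68 ± 0.47, adjusted p = 9.8e-07, after centring), the glycolytic enolase ENO2 by 6.26, NDRG1 by 5.90 and the oxygen-sensing hydroxylase EGLN3 by 5.21. The lipid droplet gene HILPDA (5.15), NDUFA4L2 (5.06), the glycolysis regulator PFKFB4 (5.01) and TMEM74B (5.16) rose too. VEGFA rose by 3.47, BNIP3 by 4.17 and HMOX1 by 4.08. The hyaluronan receptor LYVE1 (-2.84) and the adrenergic receptor ADRA2A (-2.71) fell. Also lower were SNRNP25 (-2.67), AAGAB (-2.64), SNPH (-2.64), the ribosome assembly gene NOL6 (-2.63) and the dolichol kinase DOLK (-2.51).

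Of the hypoxia-inducible genes outside glycolysis 28 of 33 rose and 0 fell, 31 adjusted over the list alone (camera adjusted p = 7.1e-67; adjusted p = 0.116 with an estimated correlation, and after centring 31 up). Glycolysis genes rose in 14 of 15, also adjusted over the list alone, with ALDOC at 4.74 and PDK1 at 2.75 (camera adjusted p = 5.5e-35; adjusted p = 0.116 with an estimated correlation). NF-kB and cytokine genes rose in 9 of 16 and fell in 1, the same adjusted over the list alone, with TNFAIP3 (2.64) and PTGS2 (2.55) up and CCL2 (-1.58) down (camera adjusted p = 9.2e-05; adjusted p = 0.639 with an estimated correlation, and after centring 8 up and 1 down). The unfolded protein and integrated stress response list rose in 6 of 21, 8 adjusted over the list alone, with the chaperone HSPA5 at 2.36 and DDIT3 at 2.43 (camera adjusted p = 0.00232; adjusted p = 0.985 with an estimated correlation, and after centring 13 up). These genes took 1.39, 2.02 and 3.46% of the reads of EHT hypoxia replicates 1, 2 and 3. Without replicate 3 the adjusted p of the list was 0.255, and HSPA5 stood at 1.56. Cardiomyocyte markers rose in 6 of 8, 7 adjusted over the list alone (camera adjusted p = 7.5e-06; adjusted p = 0.639 with an estimated correlation and 0.405 after centring). Without EHT hypoxia replicate 2 the camera adjusted p was 0.0634. After centring 1 of them was called, RYR2 (1.76, adjusted p = 0.01), and TNNT2 (2.07, adjusted p = 5.4e-04) was not (1.92, adjusted p = 0.212). NPPA differed by 2.76 (adjusted p = 1.8e-06) and after centring by 2.61 (adjusted p = 0.287), with no NPPA read in either EHT library numbered 3. Of the sarcomere and Z-disc genes 13 of 26 rose and 1 fell, with 16 and 1 adjusted over the list alone, DES by 3.46 and TCAP by 2.50 (camera adjusted p = 2.2e-07; adjusted p = 0.723 with an estimated correlation and 0.115 after centring, when 6 were up and 2 down). The sarcomere and Z-disc list took 0.322 ± 0.115% of reads in EHT normoxia and 0.230 ± 0.0727% in EHT hypoxia (SD, n = 3, exact permutation p = 0.3, two-sided). Immediate early genes rose in 5 of 17, 8 adjusted over the list alone, with EGR2 at 1.80 (camera adjusted p = 0.0126; adjusted p = 0.985 with an estimated correlation and 0.16 after centring, when 4 were up). Without EHT normoxia replicate 3 the camera adjusted p of that list was 0.174. When 1 library was left out, calls were lost for TNNT2 (adjusted p = 0.0684 to 0.381) without EHT hypoxia replicate 1 or 2 or EHT normoxia replicate 3, for NPPA (adjusted p = 0.063 to 0.168) without EHT hypoxia replicate 1 or 2 or EHT normoxia replicate 3, for RYR2 (1.61, adjusted p = 0.0835) without EHT normoxia replicate 2, for CCL2 (adjusted p = 0.0539 to 0.237) without EHT hypoxia replicate 2 or EHT normoxia replicate 1 or 2 and for EGR2 (adjusted p = 0.0597 to 0.0731) without EHT normoxia replicate 2 or 3.

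The limma fit called 1128 genes with Benjamini-Hochberg adjustment, 858 up and 270 down, and after centring 4292, of which 2360 were up and 1932 down, with 1032 called both ways. The count was 571 without EHT normoxia replicate 2, 654 without EHT hypoxia replicate 1, 685 without EHT hypoxia replicate 2 and 695 without EHT normoxia replicate 3.

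The interaction asked whether hypoxia acted differently in the 2 cultures, and its value is the hypoxia difference in EHT minus that in monolayer. Across genes the hypoxia differences of both cultures correlated with Pearson r = 0.372 and Spearman rho = 0.382, where genes are not independent replicates. Of the genes called, 242 rose in both cultures against 38.0 expected from independent calls, and 152 fell in both against 53.8. After centring the counts were 1451 against 657 and 749 against 360. CA9 rose more in EHT, with an interaction of 5.65 ± 0.68 (SE, n = 3 per group, adjusted p = 4.6e-14; 4.95 ± 0.66, adjusted p = 3.6e-04, after centring), as did EGLN3 (3.52), ENO2 (3.72), ALDOC (3.31) and BNIP3 (2.19). In normoxia CA9 and BNIP3 differed between EHT and monolayer by -4.07 and -2.09. In hypoxia CA9 differed by 1.58 (limma adjusted p = 0.0123) and BNIP3 by 0.10 (adjusted p = 0.94). The interaction of BNIP3 thus came with a lower normoxia value in EHT, without a higher hypoxia value. VEGFA rose in both and its interaction did not pass (1.06, adjusted p = 0.384). The epithelial genes KRT5 (9.36), COL17A1 (9.05), KRT17 (7.48), KRT15 (7.46), MPZL2 (6.72), PVRL4 (6.62) and the connexin GJB2 (6.61) were among the highest interactions. GABRP, with no read in EHT normoxia, had a fitted value of 7.91, between those of COL17A1 and KRT17. In EHT hypoxia replicate 3 each of these 8 genes lay below its value in both other EHT hypoxia libraries, KRT5 at 4.12 against 8.26 and 8.40. The interaction of BNIP3 lost its call (adjusted p = 0.0535 to 0.133) without monolayer hypoxia replicate 1 or 2, monolayer normoxia replicate 3, EHT hypoxia replicate 1 or EHT normoxia replicate 2 or 3.

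**Figure D4:**
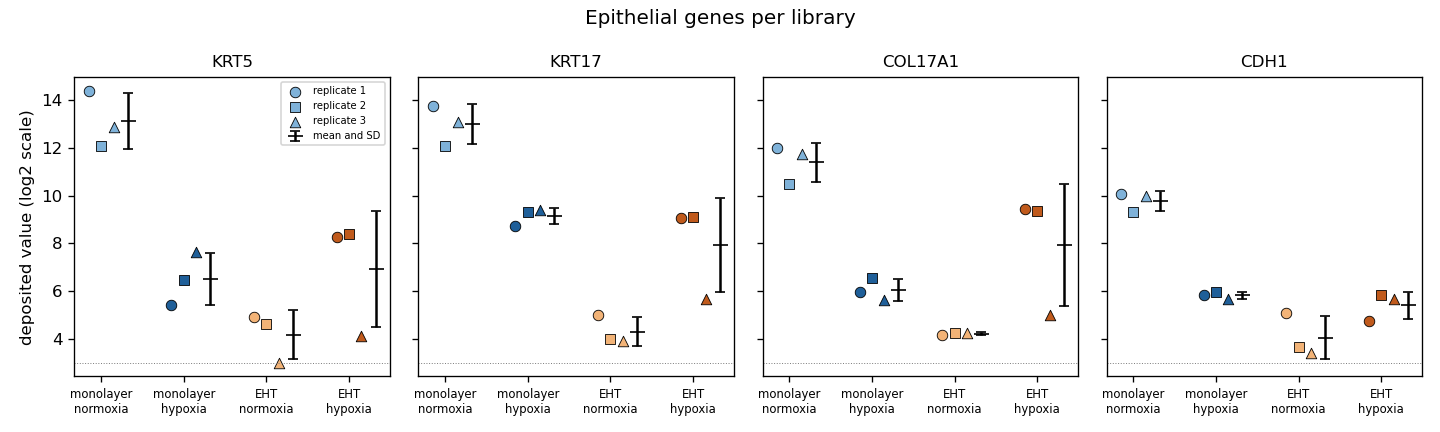
Deposited values (log2 scale) of 4 epithelial genes in each library; shapes mark the replicate number, bars give the mean and SD of 3 libraries, and the dotted line marks 0 reads. The monolayer normoxia libraries lie above all 9 others for each gene, as for CDH1 at 9.30 to 10.1.

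A negative interaction is a lower hypoxia difference in EHT. LTBP2 differed by -4.17, IGFBP7 by -3.28, and the actin regulator MICAL2 by -3.69. DPYSL3 (-3.30), the potassium channel subunit KCNMB1 (-3.28), TMEM59L (-3.78), the BMP antagonist CHRDL1 (-3.07) and CDKN1A (-2.11) were negative too. In the collagen and matrix list 5 of 29 were negative and 2 positive, with 6 and 3 adjusted over the list alone, NID1 at -3.03 and BGN at -2.70 (camera adjusted p = 1.4e-06; adjusted p = 0.727 with an estimated correlation and 0.0348 with centring as well, and after centring 17 negative and 2 positive). The p53 list was negative in 4 of 21, 6 adjusted over the list alone, with MDM2 at -2.27 (camera adjusted p = 4.1e-07; adjusted p = 0.727 with an estimated correlation, and after centring 13 negative). Cell cycle genes were positive in 10 of 30, 24 adjusted over the list alone, with RRM2 at 3.43 and MCM3 at 2.84 (camera adjusted p = 1.6e-05; adjusted p = 0.744 with an estimated correlation, and after centring 8 positive and 2 negative). Cholesterol synthesis genes were positive in 9 of 19, 16 adjusted over the list alone, with HMGCS1 at 3.03 (camera adjusted p = 8.6e-06; adjusted p = 0.744 with an estimated correlation, and after centring 13 positive). Immediate early genes were positive in 9 of 17, 10 adjusted over the list alone, with EGR1 at 5.59 and FOS at 4.19 (camera adjusted p = 8.6e-06; adjusted p = 0.727 with an estimated correlation, and after centring 6 positive). Without monolayer normoxia replicate 3, the library of its group with the highest share of these reads, EGR1 stood at 4.16, FOS at 2.80 and the adjusted p of the list at 0.00693. Epithelial markers were positive in 5 of 6, with 5 positive and 1 negative adjusted over the list alone (camera adjusted p = 4.7e-14; adjusted p = 0.00564 with an estimated correlation and 0.259 with centring as well, and after centring 5 positive and 1 negative). When 1 library was left out, calls were lost for CDKN1A (adjusted p = 0.0514 to 0.136) without monolayer hypoxia replicate 2 or 3, monolayer normoxia replicate 2, EHT hypoxia replicate 1 or 2 or EHT normoxia replicate 1 or 2 and for MDM2 (adjusted p = 0.0501 to 0.0692) without monolayer hypoxia replicate 2, monolayer normoxia replicate 2, EHT hypoxia replicate 1 or EHT normoxia replicate 1.

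The limma fit called 1249 interactions with Benjamini-Hochberg adjustment, 1147 positive and 102 negative. After centring 2956 passed, 1248 positive and 1708 negative, with 906 called both ways. The count was 746 without EHT normoxia replicate 2, 755 without monolayer hypoxia replicate 2, 766 without monolayer hypoxia replicate 1 and 1897 without monolayer normoxia replicate 1. HMOX1 (2.18, adjusted p = 0.0193) lost its call after centring (1.48, adjusted p = 0.0862), and DES (3.35, adjusted p = 3.5e-05) did as well (2.65, adjusted p = 0.226). When 1 library was left out, calls were lost for HMOX1 (adjusted p = 0.0702 to 0.251) without monolayer hypoxia replicate 1 or 2, monolayer normoxia replicate 3, EHT hypoxia replicate 3 or EHT normoxia replicate 2 and for DES (2.82, adjusted p = 0.0881) without monolayer normoxia replicate 3. Further lists were called by camera and are given with members positive and negative. In parentheses stand the same counts after centring and the adjusted p with an estimated correlation. Called positive were glycolysis 4 and 0 (5 and 2, 0.744), epicardial markers 4 and 0 (3 and 0, 0.359), pluripotency markers 3 and 0 (2 and 0, 0.359) and endoderm or hepatic markers 2 and 0 (1 and 0, 0.727). Called negative were natriuretic peptides and stretch response 2 and 2 (1 and 5, 0.722), oxidative phosphorylation 0 and 0 (0 and 18, 0.744), matrix remodelling 2 and 1 (1 and 9, 0.744), cardiomyocyte markers 0 and 1 (0 and 0, 0.727) and smooth muscle markers 1 and 2 (1 and 6, 0.633). Of these lists, calls were lost for glycolysis (adjusted p = 0.0619 to 0.0667) without monolayer normoxia replicate 2 or 3 and endoderm or hepatic markers (adjusted p = 0.0619 to 0.0664) without either of these or EHT hypoxia replicate 3. They were lost as well for natriuretic peptides and stretch response (adjusted p = 0.082 to 0.0879) without EHT hypoxia replicate 3 or monolayer normoxia replicate 3 and matrix remodelling (adjusted p = 0.0633) without EHT normoxia replicate 3. For cardiomyocyte markers they were lost (adjusted p = 0.105 to 0.727) without monolayer normoxia replicate 3, EHT hypoxia replicate 3 or EHT normoxia replicate 1.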

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

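The counts of other groupings were planned, and the tests on scaling, abundant genes, cardiomyocyte share, libraries numbered 3 and the added epithelial list were chosen after the result was seen. The interaction test called 1249 genes on the deposited values, 1147 positive and 102 negative. After centring it called 2956, 1248 positive and 1708 negative, and 906 genes were called both ways. Oxygen and the medium change cannot be told apart in it. Of 100 assignments of the libraries on the deposited values, 1 gave as many as 1249, the real one, and the highest other gave 673. Reassigning oxygen labels within a culture also breaks its hypoxia differences, which widens the spread within groups. The real assignment could rank highest for that reason alone, so this count does not exclude chance for the interaction. A list count as large as the real 15 came from 70 of 100 assignments, with 27 the highest, so chance cannot be excluded for the number of lists.

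By list, on the deposited values, the interaction was called for 4 p53 targets, 10 cell cycle genes, 9 immediate early genes, 9 cholesterol synthesis genes, 7 collagens and matrix genes and 5 epithelial markers. The gene values below are on the same scale. Centring added -0.70 to each, and HMOX1 and DES lost their calls. The interaction was 5.65 for CA9, 3.52 for EGLN3, 3.72 for ENO2, 3.31 for ALDOC, 2.19 for BNIP3 and 2.18 for HMOX1. It was 9.36 for KRT5, 9.05 for COL17A1, 7.48 for KRT17, 7.46 for KRT15, 6.72 for MPZL2, 6.62 for PVRL4 and 6.61 for GJB2. GABRP, with no read in EHT normoxia, had a fitted value of 7.91, which is no bound. It was -4.17 for LTBP2, -3.28 for IGFBP7, -3.69 for MICAL2, -3.30 for DPYSL3, -3.28 for KCNMB1, -3.78 for TMEM59L, -3.07 for CHRDL1 and -2.11 for CDKN1A. The list examples were at -3.03 for NID1, -2.70 for BGN, -2.27 for MDM2, 3.43 for RRM2, 2.84 for MCM3, 3.03 for HMGCS1, 5.59 for EGR1, 4.19 for FOS and 3.35 for DES.

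For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In genes, the real split gave 3424 for EHT against monolayer in normoxia with 0 as the highest other, 1553 in hypoxia with 1, 2945 for hypoxia in monolayer with 0, and 1128 for hypoxia in EHT with 153, each the 1 split that large. In lists, 2, 5, 3 and 10 splits were as large as the real 25, 21, 23 and 7, with highest others of 28, 25, 23 and 24. The median of the other splits was 17, 20, 19 and 12 lists, so other splits called many lists in each of these comparisons.

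More genes were lower than higher in EHT against monolayer in normoxia, and in hypoxia against normoxia in monolayer. A few abundant genes were argued against, since the reads left outside the 10 most abundant genes made up at most 37.6% of the median difference. Libraries of 1 group differed in scale, where 1 number per library removed 48.1% of the median residual SD. That spread does not test a shift between groups, and centring evens the 2 directions by construction. The deposited scaling factors, divided by median-of-ratios factors, were 1.12, 0.9425 and 0.412 in monolayer normoxia replicates 1, 2 and 3. They were 0.961, 1.42 and 1.29 in EHT normoxia and 1.36, 1.07 and 0.787 in monolayer hypoxia. The shift went the way of these factors, and in size they cover the median log2 differences of -0.66 and -0.48 in the 2 comparisons. Median-of-ratios scaling, like centring, takes out any shift shared by most genes. Whether a real change of that kind lay behind the shift cannot be told. Total RNA per cell was not measured here, so a change in it was not tested. Without monolayer normoxia replicate 3, the library with the highest median, 523 genes were higher and 1958 lower in the first comparison, and 1115 and 1311 in the second.

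Cardiomyocyte markers were lower in EHT than in monolayer in normoxia in 6 of 8 (camera adjusted p = 4.3e-08; adjusted p = 0.222 with an estimated correlation). A lower share of cardiomyocytes would lower all markers alike, and 2 of 8, PLN (0.91, 95% interval -0.94 to 2.76) and NPPA (1.18, -2.73 to 5.08), lay wholly above the list median of -3.23 after centring. PLN did so whichever of the 6 libraries was left out, but without monolayer normoxia replicate 1 or 3 or EHT normoxia replicate 1 or 2 the interval of NPPA began at -3.23, -4.14, -4.10 and -3.69 against list medians of -3.19, -3.86, -3.27 and -3.21, so a lower share and lower expression per cell cannot be told apart, nor for the other 6 markers, whose differences spanned 2.45 log2 units with no interval that excluded their median. Without the normoxia libraries numbered 3 the list median was -3.51, which argues against those libraries as the source. Regulation by culture format, which the design names, stays open and untested.

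Epithelial genes were higher in monolayer normoxia than in the other groups. After centring, 81.0% of an added basal epithelial list, 17 of 21 genes, were higher in all 3 monolayer normoxia libraries than in all 9 others. Of all tested genes 9.10% were. On the deposited values 16 of the 21 were. Epithelial cells in those cultures may account for this. The list was written after the pattern was seen, and it cannot set such cells apart from expression of these genes by other cells. Genes already seen in the named results had been taken off that list, which with them gave 24 of 28. Its most abundant genes were CDH3 at 504 and BCAM at 374 CPM (reads scaled to library totals), KRT5 stood at 1837 ± 2074 (SD, n = 3), and 18 of the 21 genes had at least 1 CPM on average outside that group. Expression of these genes by the cardiomyocytes themselves was not tested and stays open.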

How the results depend on the processing

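Median-of-ratios scaling, voom, the omission of both EHT libraries numbered 3, alone or with centring, and centring with an estimated correlation were chosen after the result was seen. Counts are given in the order of EHT against monolayer in normoxia and in hypoxia, hypoxia in monolayer and in EHT, and the interaction; the cause was not tested for any count that moved. By quantile normalization 5486, 4616, 5605, 4328 and 3141 genes were called, by centring 4984, 4602, 5615, 4292 and 2956, by median-of-ratios scaling 5302, 4855, 5812, 4583 and 3265, by voom 5679, 4245, 6213, 4181 and 2996, with array weights, whose fit did not converge, 7748, 7477, 10667, 5521 and 6451, and by centring without both EHT libraries numbered 3 5625, 4933, 6739, 5223 and 4264. Of at least 2-fold, the last 2 comparisons had 1972 and 2268 by quantile normalization, 1961 and 2048 by centring and 2771 and 2973 by centring without both EHT libraries numbered 3. Counts at 2-fold or more for EHT against monolayer in hypoxia and for those 2 comparisons were 2416, 2132 and 2279 by median-of-ratios scaling, 2433, 2312 and 2189 by voom and 2716, 2769 and 3867 with array weights.

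Lists called were 2, 4, 1, 0 and 1 with an estimated correlation, 0, 0, 1, 0 and 1 with centring as well, that of collagens and extracellular matrix in both cases, and 13, 5, 4 and 3 by fry in the last 4 comparisons. Quantile normalization called 14 lists for EHT against monolayer in normoxia, 8 for hypoxia in monolayer and 8 for the interaction. Median-of-ratios scaling called 15 and 13 for EHT against monolayer in normoxia and for hypoxia in monolayer, and for the latter centring called 13, or 15 without both EHT libraries numbered 3. With the replicate number as a block, 4416, 2082, 3831, 1784 and 1853 genes were called.

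Leaving out each library in turn gave 2356 to 4458, 922 to 1340, 1611 to 3571, 571 to 1475 and 746 to 1897 genes, and 23 to 25, 17 to 23, 16 to 23, 7 to 12 and 12 to 20 lists. The count of lists for hypoxia in EHT was 12 without EHT hypoxia replicate 3. The counts of genes at 2-fold or more had the same ranges.

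NPPA in EHT against monolayer turned to -1.13 in normoxia and 0.43 in hypoxia with array weights. In hypoxia it ranged from -3.04 without EHT hypoxia replicate 2 to 0.98 without EHT hypoxia replicate 3. It was 0.98 without both EHT libraries numbered 3, and 1.26 with centring as well. PLN in normoxia turned to -1.36 with array weights. For hypoxia in monolayer, the median of ribosomal protein genes turned to -0.26 by quantile normalization and that of atrial markers to 0.34 by centring, with or without an estimated correlation. The median of cardiomyocyte markers in the interaction (-0.51) ranged from -1.45 without EHT normoxia replicate 3 to 0.91 without EHT hypoxia replicate 3. The cause was not tested. Of 180 results of named genes, all kept direction and call without the mean-variance trend, 169 did with centring and 179 with the replicate block, while calls were lost for 19 with the robust variance model, 15 by voom, 11 with no filter, 10 by quantile normalization, 10 by median-of-ratios scaling, 9 with centring, 7 of those run in fits to the compared groups alone, and 6 without both EHT libraries numbered 3, or 2 with centring as well. The filter on low values left 12084 of 16745 genes.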

Other observations

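The epithelial list described above was tested after its pattern was seen; the values here come from the fixed lists. Of the nuclear-encoded oxidative phosphorylation genes, 2 of 29 were lower in EHT than in monolayer in hypoxia and 0 higher, and after centring 20 were lower (camera adjusted p = 0.00567; adjusted p = 0.909 with an estimated correlation). Of the list of the TCA cycle and creatine kinase 3 of 18 were lower there, and 12 after centring (camera adjusted p = 0.00664; adjusted p = 0.785 with an estimated correlation). Of the ribosomal protein genes 17 were tested and none was called with hypoxia in either culture on the deposited scale, but 13 rose in monolayer and 11 in EHT after centring. The list was called in monolayer (camera adjusted p = 0.0341; adjusted p = 0.766 with an estimated correlation), but not without monolayer hypoxia replicate 2 (adjusted p = 0.0806) or monolayer normoxia replicate 1 (adjusted p = 0.091). Fatty acid oxidation genes were lower in EHT normoxia in 6 of 23 and higher in 1, with a median of -0.48 that turned to 0.25 after centring, when 4 were lower and 7 higher (camera adjusted p = 0.302).

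Oxidant defence genes were higher in EHT in 4 of 13 in normoxia (camera adjusted p = 5.4e-05; adjusted p = 0.516 with an estimated correlation, and 9 higher after centring) and in 4 in hypoxia (camera adjusted p = 8.9e-04; adjusted p = 0.656 with an estimated correlation and 0.15 without EHT hypoxia replicate 3, and 8 higher after centring). Interferon-stimulated genes rose in 3 of 15 and fell in 2 with hypoxia in EHT (camera adjusted p = 0.609), and after centring in 4 and 3. Endothelial markers were lower in EHT normoxia in 5 of 8 and higher in 2 (camera adjusted p = 0.181), and after centring in 3 and 2. Atrial markers with hypoxia in monolayer had a median of -0.21, while their mean and test were positive, with 3 of 9 higher and 2 lower (camera adjusted p = 0.0247; adjusted p = 0.671 with an estimated correlation and 0.894 after centring, and 0.502 without monolayer normoxia replicate 3). Macrophage or leukocyte markers fell in 4 of 9 with hypoxia in monolayer and in 0 after centring (camera adjusted p = 0.116). Their median was -1.09, and -1.80 without monolayer normoxia replicate 1, when the list was called (adjusted p = 0.0109). They took 0.00472, 0.0435 and 0.00634% of the reads of monolayer normoxia replicates 1, 2 and 3.

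Hypoxia-inducible genes outside glycolysis took 0.563% of reads in monolayer normoxia and 2.48% in monolayer hypoxia, 0.616% in EHT normoxia and 3.63% in EHT hypoxia (means of 3 libraries). The 10 most abundant genes took 9.29% to 20.6% of the reads of a library. Mitochondrially encoded genes could not be tested.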
